A study of Homo sapiens with 8 samples.

How the data were processed

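Total RNA of 8 cultures of HEK wild-type cells, 4 treated with 16 µM geneticin and 4 untreated, was measured on 1 expression array each. Per the labels' protocols, cells were grown in DMEM with 10% serum and then kept in F10 medium with 15 µg/mL saponin, with or without geneticin, for 32 h. RNA was extracted with Trizol and treated with DNase, and biotinylated cDNA was made from 200 ng of total RNA with whole-transcript labelling kits. Per the submitters' processing notes, Affymetrix Expression Console 1.1 and the RMA method were used, so the deposited log2 values had been background corrected, quantile normalized and summarised per probe set by the authors. The range of the values and their near equal medians fit that scale. No further normalization was applied, and the filters used by the authors on probe sets, if any, and the test behind their adjusted p are not given in the sources used here.

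Every column of the table was matched to 1 sample, with 0 left over. Of the probe sets, 19460 were annotated to exactly 1 gene, 1754 to several genes and 12083 to none. Probe sets of several genes or of none, controls included, were left out of the main test, and where a gene had several probe sets (769 genes) the probe set with the highest mean over all 8 arrays was kept, which left 18417 genes. Symbols were looked up in a RefSeq table of GRCh38.p14, used for names, neighbours and genomic span alone. 31 symbols had no entry and 0 needed an update. No coordinates are given, since the files name no genome build.

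Groups followed the labels, geneticin against untreated, and no replicate block was used. A linear model per gene with moderated variances (limma 3.58.1 with statmod 1.5.0, in R 4.3.3) gave two-sided p-values, adjusted by the Benjamini-Hochberg method over all genes, and an adjusted p under 0.05 was called a change. The fold threshold of 1.2 that the series states was applied as a further count. Errors are standard errors (SE) of the log2 fold change from the model, and log2 fold changes are geneticin minus untreated. The number of arrays limits the precision. Sample structure was described by principal components of gene-centred values, with an exact permutation test over the 35 ways to split 8 arrays into 4 and 4.

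The genes to name, 34 gene lists, the tests and most other settings were chosen before the data were examined. Named were the 12 genes with the largest rise and the 12 with the largest fall among those that changed and whose groups did not overlap. Up to 4 members of each list with the lowest p were also named. Among the largest rises and falls, symbols with prefixes of small RNAs, olfactory receptors or unnamed genes were to be passed over, which removed 0. Further genes, said to be named after their values were seen, are members that moved against their list and members of gene families. The lists covered ATF4 and the amino acid response, endoplasmic reticulum chaperones and the unfolded protein response, cytosolic heat shock, cytosolic aminoacyl-tRNA synthetases, cholesterol synthesis and SREBP2, fatty acid synthesis and SREBP1, the lysosome, autophagy, p53 targets, nonsense-mediated decay factors, noncoding snoRNA host genes, cytosolic ribosomal proteins, ribosome assembly, translation factors and mitochondrially encoded transcripts. They also covered the mitochondrial ribosome, the nuclear encoded respiratory chain, glycolysis and hypoxia, NRF2 and oxidative stress, metallothioneins and the zinc response, immediate early genes, NF-kB and inflammatory cytokines, the interferon response, mitosis and G2/M, DNA replication and S phase, replication-dependent histones, the proteasome, phosphoinositide and calcium signalling, extracellular matrix and adhesion, and lineage markers that HEK cells express. Markers of fibroblasts, keratin epithelium, blood cells and hepatocytes stood for other cell types.

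Each list was counted member by member from the fit of all genes and again with p adjusted over the list alone. It was then tested against all other genes with limma's camera at a preset correlation between genes of 0.01, adjusted over the 33 lists with measured members. Camera with an estimated correlation, the self-contained fry test and a rank version of camera were run beside it. The model was tested on simulated data with each gene's own mean and within-group spread and independent genes, where it recovered 22.4%, 85.1% and 97.0% of genes planted at 1.2-fold, 1.5-fold and 2-fold, with 6 false calls. A planted shift of 0.2 in 46 genes was called by camera with either correlation, with 0 other lists called. The genes were independent there too, so this does not show how camera fares with correlated genes. In the ATF4 list the estimated correlation between genes was 0.45.

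Results were recomputed with a replicate block by the number in the labels, quantile normalization again, median centring, the brighter genes alone (mean above the median of all genes), every probe set, the mean of a gene's probe sets, a trended robust prior, no moderation, array weights, a fold of 1.5, limma's treat test against a fold of 1.2, and without each array in turn. An exact permutation of list scores, random lists matched on mean level and families of genes sharing a symbol stem were added after seeing the data. Single arrays far from the rest of their group were sought with Dixon's test.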

Results

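Gene expression was measured in HEK wild-type cells, a human embryonic kidney line, after 32 h in F10 medium with 15 µg/mL saponin, a detergent that makes membranes permeable. 4 cultures received 16 µM geneticin (G418), an aminoglycoside that binds ribosomes, and 4 did not. The labels describe the arrays of each group as biological replicates, so n = 4 per group throughout. The comparison asks which transcripts differed between treated and untreated cultures. All 8 arrays gave a value for every probe set, and the median over the 18417 genes tested lay between 7.50 and 7.59 on the log2 scale on every array. The number of arrays limits the precision.

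In geneticin-treated cells 18 of 22 measured cytosolic heat shock genes and 19 of 31 genes of the endoplasmic reticulum chaperone list rose, and 27 of 40 genes of the ATF4 and amino acid response list fell (camera adjusted p = 1.8e-18, 2.0e-13 and 6.2e-12, and 0.163, 0.313 and 0.357 with an estimated correlation). DNAJB1, a co-chaperone of cytosolic HSP70 (probe set 8034837), rose by a log2 fold change of 1.68 ± 0.10 (SE, n = 4 per group), or 3.21-fold, with a limma adjusted p of 4.5e-05. HSPH1, a nucleotide exchange factor of HSP70 (probe set 7970864), rose 2.70-fold, and its log2 fold change of 1.43 ± 0.06 had the smallest adjusted p of all genes (3.5e-06, limma). HSPA5, the main HSP70 chaperone of the endoplasmic reticulum (probe set 8164165), rose 2.61-fold from a mean of 11.44 to 12.82 on the log2 scale (adjusted p = 5.2e-05, limma). In the other direction, and both of the ATF4 list, NUPR1, a stress-responsive chromatin protein (probe set 8000574), fell by 1.60 on the log2 scale (SE 0.23), or 3.03-fold, with a limma adjusted p of 0.00153. SLC6A9, a glycine transporter (probe set 7915543), fell by 1.40 on the log2 scale (SE 0.15, adjusted p = 5.0e-04, limma).

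The other large rises included 2 more proteins of the endoplasmic reticulum, the disulfide isomerase PDIA4 (2.52-fold, adjusted p = 2.2e-04, limma) and SDF2L1 (2.38-fold, adjusted p = 3.1e-04). CHORDC1, an HSP90 co-chaperone, rose 2.73-fold (adjusted p = 0.00524). Respiratory chain subunits were also among them, with COX7B of complex IV and NDUFB6 of complex I each 2.38-fold higher (adjusted p = 0.00267 and 0.00109). SELENOW, a small selenoprotein, rose 2.70-fold, TAF13, a subunit of the transcription factor TFIID, 2.53-fold, and STX1A, a SNARE protein of exocytosis, 2.36-fold (adjusted p = 6.3e-04, 2.8e-04 and 8.5e-05). HSPA1L had the largest rise, 4.30-fold (adjusted p = 1.8e-04). It lies beside HSPA1A and HSPA1B, inducible HSP70 genes of related sequence that had no probe set of their own, and whether its probe set also reads their transcripts is not given in the sources used here.

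Among the large falls were SLC7A11, the cystine and glutamate exchanger (2.87-fold lower, adjusted p = 0.00547, limma), ALDH1L2, a mitochondrial folate enzyme (2.14-fold, adjusted p = 0.00477), and PCK2, the mitochondrial PEP carboxykinase (2.03-fold, adjusted p = 0.00163). ASS1, which makes argininosuccinate for arginine synthesis, fell 2.29-fold (adjusted p = 4.6e-04). DDIT4, an inhibitor of mTORC1 signalling, fell 2.16-fold and ISYNA1, which makes inositol phosphate from glucose phosphate, 2.14-fold (adjusted p = 0.00220 and 0.00111). Others were EOLA1-DT, a noncoding transcript (2.43-fold), ABRAXAS1, a scaffold of the BRCA1-A complex (2.26-fold), BEST1, a chloride channel (2.19-fold), and SGF29, a histone reader of the SAGA complex (2.03-fold), with adjusted p of 8.5e-05, 5.0e-04, 5.1e-04 and 1.2e-04. Without moderation of the variances, 3 of the 24 genes named so far no longer passed: CHORDC1 (adjusted p = 0.0594, over all alternatives 0.00186 to 0.0594), SLC7A11 (0.0609, 0.00309 to 0.0609) and ALDH1L2 (0.0550, 0.00169 to 0.0550).

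**Figure D1:**
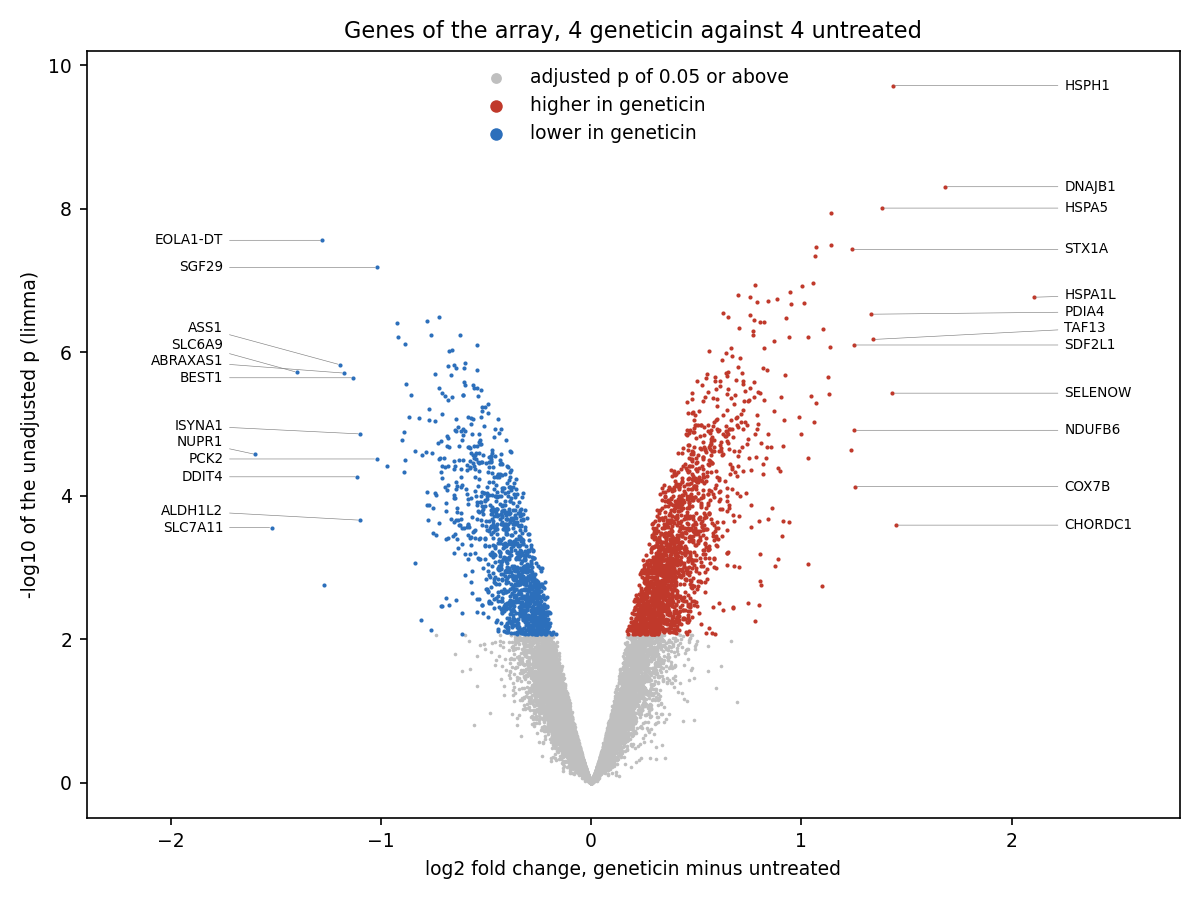
Each point is 1 of 18417 genes, with the log2 fold change (geneticin minus untreated, 4 arrays each) on the x axis and the negative log10 of limma's unadjusted p on the y axis. Red points are the 1873 genes that rose and blue points the 1266 that fell at an adjusted p under 0.05, and the 24 named genes reach from 2.10 for HSPA1L to -1.60 for NUPR1.

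At an adjusted p under 0.05 (limma), 3139 of 18417 genes changed, 1873 higher and 1266 lower in geneticin. Of these, 2715 changed by over 1.2-fold, the threshold the series states, with 1629 higher and 1086 lower, and 386 by over 1.5-fold. Most changes were small, with a median absolute log2 fold change of 0.37 among changed genes against a median SD between replicates of 0.11 in either group. Over 2-fold, 31 genes rose and 13 fell. For 20.1% of all genes the groups did not overlap, where chance gives 2.86%. The count was 1941 without untreated replicate 3 and 1723 without moderation of the variances, and 208 genes passed limma's test against a fold of 1.2.

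Treatment was the main axis of variation between the arrays. Principal component 1 held 51.3% of the variance, and 86.8% of its variance lay between the groups (exact permutation p = 0.0286, two-sided, the smallest that 35 splits can give). Component 2 held 17.5%. On component 1 untreated replicate 2 (-4.95) lay nearer the treated arrays (8.44 to 21.41) than the other untreated arrays did (-21.45 to -14.44). It also had the largest value on component 2 (20.71). Pearson correlations across genes, which are not independent replicates, ran from 0.992 to 0.997 within the untreated group, from 0.995 to 0.997 within the geneticin group and from 0.985 to 0.994 between groups.

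Chaperone genes rose in both compartments. Of 22 measured genes of the cytosolic heat shock list, 18 rose, 0 fell and 4 did not pass, and adjusted over the list alone 18 rose and 0 fell. Over all settings 14 to 19 rose. Besides HSPH1 and DNAJB1, BAG3, an HSP70 co-chaperone, rose by 1.14 ± 0.07 and DNAJB4 by 1.06 ± 0.08 on the log2 scale (SE, n = 4, limma adjusted p = 5.2e-05 and 9.3e-05). The list median was 0.65 (camera adjusted p = 1.8e-18, adjusted p = 0.163 with an estimated correlation). In the endoplasmic reticulum chaperone and unfolded protein response list, 19 of 31 measured genes rose, 1 fell and 11 did not pass, and adjusted over the list alone 23 rose and 1 fell. Counts over all settings were 13 to 21 rising and 0 to 2 falling. HSPA5 and PDIA4 were joined by the co-chaperone DNAJB11 (1.14 ± 0.08, adjusted p = 8.5e-05) and the secreted stress protein MANF (2.15-fold, adjusted p = 2.5e-04). The median was 0.49 (camera adjusted p = 2.0e-13, adjusted p = 0.313 with an estimated correlation). DNAJC10, a disulfide reductase of the same compartment named here after its values were seen, fell by 0.30 (adjusted p = 0.0226), a call lost without untreated replicate 3 or 4, without geneticin replicate 2 or 3 (adjusted p up to 0.0677) or without moderation.

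**Figure D2:**
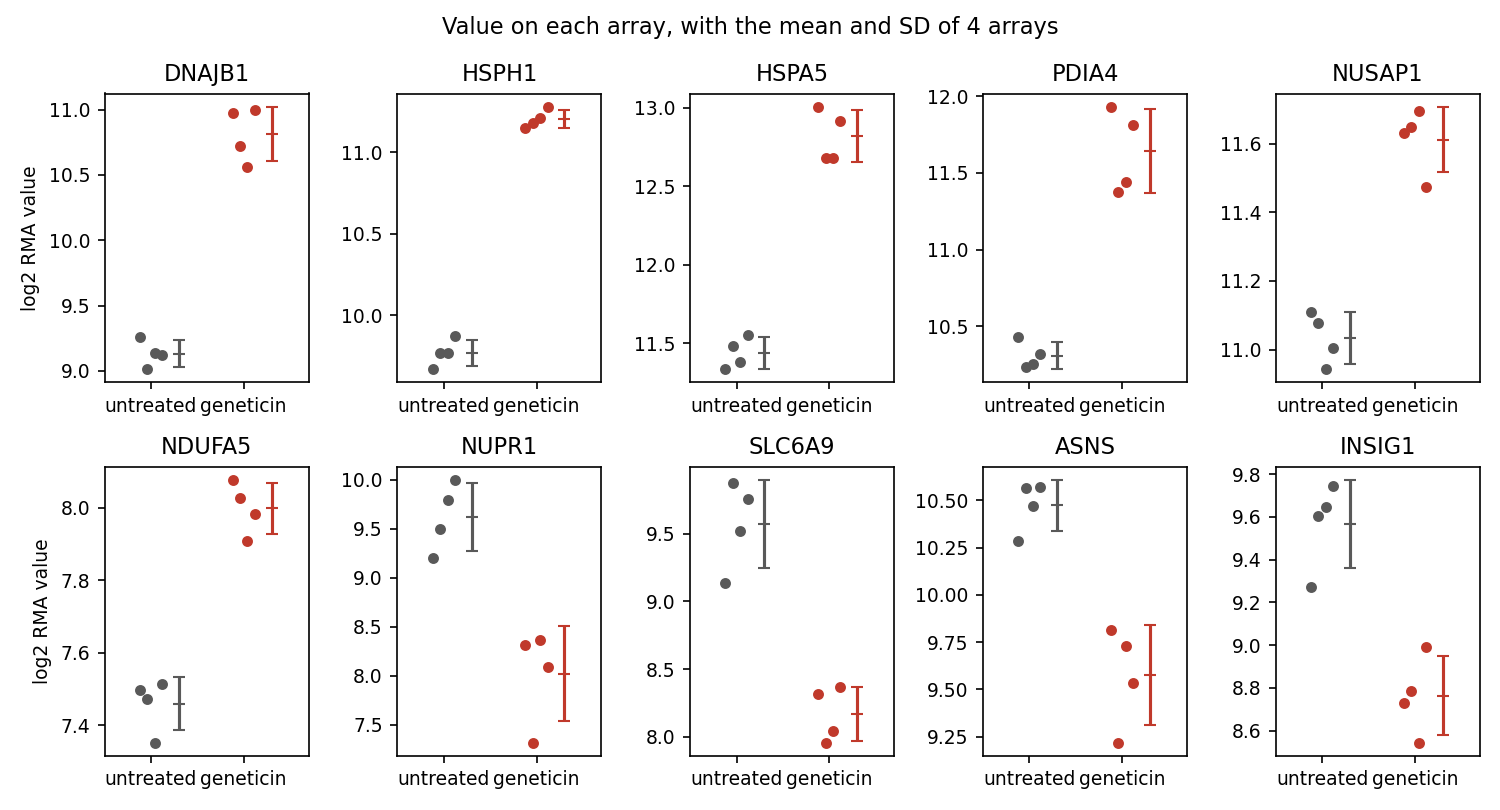
Each point is the log2 RMA value of 1 array, grey for untreated and red for geneticin, with the mean and SD of 4 arrays beside the points, for 10 genes on separate y axes that do not start at 0. HSPA5 has a mean of 11.44 in untreated and 12.82 in geneticin, and NUPR1 a mean of 9.62 and 8.02.

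The ATF4 and amino acid response list fell. In it 27 of 40 measured genes fell, 2 rose and 11 did not pass, and adjusted over the list alone 28 fell and 2 rose. Over all settings 14 (without moderation) to 28 fell. ASNS, asparagine synthetase, fell by 0.90 (SE 0.12), PHGDH, which opens serine synthesis, fell by 0.76 (SE 0.11), and PYCR1, which completes proline synthesis, fell by 0.73 (SE 0.10) on the log2 scale (limma adjusted p = 0.00124, 0.00150 and 0.00133). The list median was -0.48 (camera adjusted p = 6.2e-12, adjusted p = 0.357 with an estimated correlation). In the list's mean centred value untreated replicate 1 (0.01) stood apart from the other untreated arrays (0.23 to 0.44). It lay nearer to geneticin replicate 1 (-0.12), though the groups did not overlap. The 2 members that rose, named after their values were seen, were PPP1R15A, which directs dephosphorylation of eIF2α (0.74 ± 0.12, adjusted p = 0.00299), and DDIT3, the transcription factor CHOP (0.56 ± 0.17, adjusted p = 0.0434). The call for DDIT3 was lost without untreated replicate 1, 3 or 4 or geneticin replicate 1 or 4 (adjusted p up to 0.111), after quantile normalization again and without moderation (adjusted p = 0.0618 and 0.167).

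Cytosolic aminoacyl-tRNA synthetases, which charge tRNAs for translation, leaned lower, with 7 of 20 measured genes falling, 1 rising and 12 not passing (12 fell and 2 rose adjusted over the list alone). Examples were LARS1 (-0.44 ± 0.09, adjusted p = 0.00885, limma), SARS1 (-0.43 ± 0.10, adjusted p = 0.0115), QARS1 (-0.43 ± 0.11, adjusted p = 0.0198) and IARS1 (-0.33 ± 0.07, adjusted p = 0.00908). RARS1, the arginyl enzyme, named after its values were seen, rose by 0.29 (adjusted p = 0.0220). The median was -0.25 (camera adjusted p = 0.00845, adjusted p = 0.718 with an estimated correlation), and the list no longer passed without untreated replicate 2 (adjusted p = 0.0803), nor by fry (adjusted p = 0.105). The groups overlapped in its mean centred value, with untreated replicate 1 and geneticin replicate 1 both at 0.01. Falling members numbered 3 without untreated replicate 4, 1 without moderation, 11 among the brighter genes and 12 after quantile normalization again, and up to 2 rose in other settings. LARS1, SARS1, QARS1 and RARS1 did not pass without moderation (highest adjusted p 0.0913, for QARS1), QARS1 did not without untreated replicate 1 or 4 (up to 0.0605), and RARS1 did not without untreated replicate 1 or 3 or geneticin replicate 1 or 3 (up to 0.0736).

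Part of the sterol synthesis and matrix genes fell. Of 21 measured cholesterol synthesis and SREBP2 genes, 8 fell, 0 rose and 13 did not pass, with 10 falling adjusted over the list alone (median -0.15, camera adjusted p = 3.1e-04, adjusted p = 0.313 with an estimated correlation). Without moderation 5 fell. INSIG1, a sterol sensor of SREBP processing, fell by 0.80 (SE 0.12), and LSS, lanosterol synthase, fell by 0.68 (SE 0.08) on the log2 scale (limma adjusted p = 0.00153 and 6.6e-04). HMGCS1 and CYP51A1, earlier and later enzymes of the pathway, had log2 fold changes of -0.56 ± 0.11 and -0.36 ± 0.06 (adjusted p = 0.00588 and 0.00299). For extracellular matrix and adhesion, 9 of 27 measured genes fell, 0 rose and 18 did not pass, 9 fell adjusted over the list alone, and the median was -0.15 (camera adjusted p = 0.00483, adjusted p = 0.664 with an estimated correlation, 0.0765 by fry). FN1, fibronectin, fell by 0.64 (SE 0.08), LAMB1 and LAMC1, laminin chains, fell by 0.58 and 0.39, and LOXL2, a collagen crosslinking oxidase, fell by 0.32 (adjusted p = 9.5e-04, 0.00526, 0.00410 and 0.00399). Only 5 matrix genes fell without untreated replicate 1 or 3 or geneticin replicate 1 or 4, and 1 rose with the replicate block. The matrix median ran from -0.23 to -0.09 with 1 array left out, and the groups overlapped in the list's mean centred value. Untreated replicate 2 (-0.06) stood apart from the other untreated arrays (0.09 to 0.15) and lay at or below geneticin replicates 1, 3 and 4 (-0.06 to 0.00). Between arrays of the same number the value was lower in geneticin each time, also for replicate 2 (-0.21 against -0.06), though a pairing by number is not established.

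The fatty acid synthesis and SREBP1 list did not pass (median -0.16, camera adjusted p = 0.0700, adjusted p = 0.549 with an estimated correlation), with 3 of 15 measured genes falling, 0 rising and 12 not passing, against 6 falling and 1 rising adjusted over the list alone. With 1 array left out the median ran from -0.18 to -0.09 and the camera adjusted p from 0.0174 to 0.164. It did pass without untreated replicate 1, geneticin replicate 1 or geneticin replicate 4 (adjusted p = 0.0174, 0.0392 and 0.0493), after quantile normalization again, among the brighter genes, by fry and by ranks (0.0244, 0.0325, 0.0494 and 0.0467). The 3 genes were FADS1, a fatty acid desaturase (-0.53 ± 0.11, adjusted p = 0.00680, limma), SREBF1, the regulator itself (-0.27 ± 0.08, adjusted p = 0.0358), and MID1IP1, an activator of acetyl-CoA carboxylase (-0.29 ± 0.08, adjusted p = 0.0254). Without moderation 0 of 15 passed, where 7 had an unadjusted limma p under 0.05. MID1IP1 also did not pass without untreated replicate 3 or 4 or geneticin replicate 2, 3 or 4 (adjusted p up to 0.0809), nor did SREBF1 without untreated replicate 1, 3 or 4 or geneticin replicate 1, 2 or 3 (up to 0.0947) or with a trended robust prior, so only 1 member fell without untreated replicate 3 or 4 or geneticin replicate 2 or 3. By contrast 5 fell after quantile normalization again, among the brighter genes or with array weights, and 1 rose with the replicate block, among the brighter genes or without untreated replicate 4.

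Both lists of nuclear genes for the respiratory chain and mitochondrial ribosome leaned higher. In the respiratory chain list 26 of 60 measured genes rose, 2 fell and 32 did not pass, and adjusted over the list alone 29 rose and 4 fell. Only 15 rose after quantile normalization again, and 4 fell without untreated replicate 2 or with array weights and 3 without geneticin replicate 4. Besides COX7B and NDUFB6, NDUFA5 and NDUFC1, both of complex I, rose by 0.54 ± 0.06 and 0.50 ± 0.07 on the log2 scale (SE, n = 4, limma adjusted p = 6.5e-04 and 0.00121). The 2 that fell were NDUFV1, the NADH-binding core subunit of complex I (-0.39 ± 0.05, adjusted p = 0.00146), and ATP5F1D of ATP synthase (-0.35 ± 0.11, adjusted p = 0.0472), the latter named after its values were seen. The list median was 0.18 (camera adjusted p = 2.1e-08, adjusted p = 0.313 with an estimated correlation). For the mitochondrial ribosome, 15 of 56 measured genes rose, 1 fell and 40 did not pass (15 and 4 adjusted over the list alone), with MRPL13 at 0.81 ± 0.07, MRPL35 at 0.54 ± 0.07, MRPL50 at 0.48 ± 0.07 and MRPL20 at 0.45 ± 0.06 (adjusted p = 2.2e-04, 0.00107, 0.00182 and 0.00111). Its median was 0.12 (camera adjusted p = 9.2e-05, adjusted p = 0.313 with an estimated correlation, 0.0773 among the brighter genes alone). After quantile normalization again the median was 0.08. Most members of this list lay above the median level of all genes, and bright genes rose more often than dim ones. The count of rising members alone is thus no measure of enrichment. The list's falling members ran from 0 to 5 over all settings, with 3 without untreated replicate 2 or geneticin replicate 4, 4 with the replicate block or after quantile normalization again and 5 with array weights. MRPL27, also a subunit of the large mitochondrial ribosomal subunit and named after its values were seen, fell by 0.27 (adjusted p = 0.0291). Its call was lost without untreated replicate 1 or 3, geneticin replicate 1, 2 or 3 or moderation (adjusted p up to 0.0809), and that of ATP5F1D without any of those arrays or untreated replicate 4, without moderation and after median centring (adjusted p up to 0.149).

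Cell division genes were higher. Of 34 measured mitosis and G2/M genes, 20 rose, 0 fell and 14 did not pass, and adjusted over the list alone 24 rose and 0 fell. Rising members numbered 14 to 24 over all settings. NUSAP1, which bundles spindle microtubules, rose by 0.58 ± 0.07, KIF20A, a kinesin of cytokinesis, by 0.42 ± 0.06, and the spindle checkpoint kinases BUB1 and BUB1B by 0.38 ± 0.06 each on the log2 scale (SE, n = 4, limma adjusted p = 6.5e-04, 0.00200, 0.00275 and 0.00351). The median was 0.31 (camera adjusted p = 2.0e-13, adjusted p = 0.275 with an estimated correlation). DNA replication and S phase genes moved less evenly, with 8 of 41 measured rising, 3 falling and 30 not passing (9 and 4 adjusted over the list alone). Without moderation 5 rose and 0 fell. PCNA, the sliding clamp, rose by 0.38 ± 0.06, CDC6, which licenses origins, by 0.52 ± 0.09, FEN1, a flap endonuclease, by 0.40 ± 0.07 and the cyclin CCNE2 by 0.54 ± 0.10 (adjusted p = 0.00193, 0.00324, 0.00502 and 0.00521). LIG1, the replicative ligase, POLD1, the catalytic subunit of polymerase delta, and MCM5, a helicase subunit, named after their values were seen, fell by 0.42, 0.32 and 0.30 (adjusted p = 0.00970, 0.0155 and 0.0271). None of these 3 passed without moderation (adjusted p = 0.0527, 0.0540 and 0.0780), and MCM5 did not pass without untreated replicate 1, 3 or 4 or geneticin replicate 2, 3 or 4 (up to 0.0729). The replication median of 0.10 had a camera adjusted p of 0.00483 and an adjusted p = 0.702 with an estimated correlation, 0.174 after quantile normalization again (median 0.04), 0.113 by fry and 0.196 among the brighter genes alone. The groups overlapped in the list's mean centred value, though geneticin was higher at every replicate number. The median lay within the central 95% of random lists of like mean level, a check chosen after seeing the data.

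Replication-dependent histone genes went both ways, with 11 of 47 measured rising, 8 falling and 28 not passing (12 and 9 adjusted over the list alone, 6 and 8 among the brighter genes, camera adjusted p = 0.604). H2AC12 rose 2.01-fold and H2AC8 by 0.46 ± 0.05, while H2BC21 and H2AC6 fell by 0.88 and 0.78 on the log2 scale (SE 0.10 and 0.07, limma adjusted p = 1.7e-04, 7.0e-04, 5.6e-04 and 2.2e-04).

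Proteasome subunits, which degrade tagged proteins, also leaned higher, with 15 of 32 measured genes rising, 1 falling and 16 not passing (18 and 1 adjusted over the list alone). PSMD12 rose by 0.74 ± 0.10, PSMB3 and PSMA5 by 0.49 ± 0.06 each and PSMD6 by 0.47 ± 0.08 on the log2 scale (SE, n = 4, limma adjusted p = 0.00133, 0.00104, 9.6e-04 and 0.00324). The median was 0.20 (camera adjusted p = 1.1e-07, adjusted p = 0.275 with an estimated correlation), and 9 genes rose without untreated replicate 3 or after quantile normalization again. Falling members numbered 0 to 2 over all settings. PSME1, part of an alternative cap of the proteasome and named after its values were seen, fell by 0.38 (adjusted p = 0.0268), a call lost without untreated replicate 1 or 3, geneticin replicate 2, 3 or 4 or moderation (adjusted p up to 0.102). In the autophagy list 8 of 32 measured genes rose, 2 fell and 22 did not pass (12 and 3 adjusted over the list alone, median 0.17, camera adjusted p = 0.00127, adjusted p = 0.450 with an estimated correlation). SQSTM1, a cargo receptor, rose by 0.50 ± 0.08 and ATG3, a lipidation enzyme, by 0.33 ± 0.05, while ULK2, an initiating kinase, fell by 0.63 (SE 0.12) and BNIP3L, a mitophagy receptor, fell by 0.30 (SE 0.07), with adjusted p of 0.00190, 0.00302, 0.00475 and 0.0130. Its rising members numbered 2 without untreated replicate 3 or without moderation, 4 without untreated replicate 1 or 4 and 5 without geneticin replicate 1 or 4, and 4 members fell without untreated replicate 2. Geneticin replicate 1 stood apart, with a mean centred value of 0.185 for the list against 0.01 to 0.03 in the other treated arrays, and without it the median was 0.12 (adjusted p = 0.0120, over all alternatives 4.4e-04 to 0.450).

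The lysosome list did not pass (camera adjusted p = 0.626), with 7 of 46 measured genes rising, 9 falling and 30 not passing (8 and 11 adjusted over the list alone). ATP6V1C1 and ATP6V1B2, subunits of the proton pump, rose by 0.57 ± 0.08 and 0.37 ± 0.06, while ASAH1, acid ceramidase, fell by 0.62 and SGSH, a heparan sulfatase, fell by 0.38 on the log2 scale (limma adjusted p = 0.00146, 0.00268, 0.00221 and 0.00268). Rising members numbered 4 without untreated replicate 1 or 4, and falling members 4 without untreated replicate 3 or geneticin replicate 2. Without moderation 4 rose and 3 fell, and with the replicate block 8 rose and 13 fell.

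Factors of nonsense-mediated decay, which removes transcripts with premature stop codons, leaned higher, with 7 of 16 measured genes rising, 0 falling and 9 not passing (8 and 0 adjusted over the list alone, 5 to 8 rising over all settings). SMG8, a regulator of the SMG1 kinase, rose by 0.77 ± 0.09, MAGOH and EIF4A3, core proteins of the exon junction complex, by 0.57 ± 0.08 and 0.35 ± 0.06, and DCP1A, a decapping factor, by 0.32 ± 0.07 on the log2 scale (SE, n = 4, limma adjusted p = 6.5e-04, 0.00134, 0.00315 and 0.0110). The median was 0.17 (camera adjusted p = 2.0e-04, adjusted p = 0.357 with an estimated correlation). In this list's mean centred value untreated replicate 2 (0.00) stood apart from the other untreated arrays (-0.19 to -0.11). It lay nearer to geneticin replicates 3 and 4 (0.06 and 0.05), though the groups did not overlap. Of 38 measured ribosome assembly genes 12 rose, 1 fell and 25 did not pass (14 and 1 adjusted over the list alone), among them NOP16 (0.54 ± 0.11), BYSL (0.50 ± 0.08) and LTV1 (0.48 ± 0.08), factors of subunit maturation, and POLR1C, a subunit of RNA polymerases I and III (0.38 ± 0.08), with adjusted p of 0.00735, 0.00314, 0.00275 and 0.00710. NOP16 did not pass without moderation (0.0554, over all alternatives 0.00164 to 0.0554), and 7 members rose without untreated replicate 3 or without moderation. BOP1, a pre-rRNA processing factor named after its values were seen, fell by 0.28 (adjusted p = 0.0161, 0.0564 without untreated replicate 3). The median was 0.12 (camera adjusted p = 0.00105, adjusted p = 0.650 with an estimated correlation, 0.0765 by fry and 0.0773 among the brighter genes alone), or 0.07 after quantile normalization again. The groups overlapped in the mean centred value of ribosome assembly, though geneticin was higher at every replicate number. Both medians lay within the central 95% of random lists of like mean level, a check chosen after seeing the data.

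The lists of cytosolic ribosomal proteins, translation factors and snoRNA host genes did not pass. Among 58 measured cytosolic ribosomal protein genes, RPS24, of the small subunit, rose by 0.64 ± 0.09 on the log2 scale (limma adjusted p = 0.00114) and 57 did not pass, the same adjusted over the list alone (camera adjusted p = 0.745). Up to 2 rose and up to 3 fell in other settings. Of 37 translation factors, 8 rose, 5 fell and 24 did not pass (10 and 6 adjusted over the list alone, 6 and 3 without moderation, camera adjusted p = 0.382). EEF2K, the kinase of elongation factor 2, fell by 0.60, EIF2S3, a subunit of eIF2, fell by 0.43, and GTPBP2 fell by 0.54 (adjusted p = 4.6e-04, 0.00177 and 0.00473). EIF2S1, another eIF2 subunit, rose by 0.35 ± 0.07 (adjusted p = 0.00543). Of 6 measured noncoding snoRNA host genes, EPB41L4A-AS1 fell by 0.64 (adjusted p = 0.00413) and 5 did not pass, also adjusted over the list alone (camera adjusted p = 0.506). With the replicate block or without untreated replicate 2 another host rose, after quantile normalization again another fell, and 9 listed hosts lay only on probe sets shared between genes. The 15 mitochondrially encoded transcripts had 0 members measured on a probe set of their own.

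Other stress and signalling lists did not pass either. Of 24 p53 targets 3 rose, 3 fell and 18 did not pass (3 and 3 adjusted over the list alone, camera adjusted p = 0.878), with TIGAR, a fructose bisphosphatase, at 0.69 ± 0.11 and PPM1D, a phosphatase, at 0.32 ± 0.06 (limma adjusted p = 0.00220 and 0.00419). Among those that fell were SPATA18, a protein of mitochondrial quality control, at -0.55 ± 0.11 and CCNG1, cyclin G1, at -0.43 ± 0.12 (adjusted p = 0.00674 and 0.0299). SPATA18 did not pass without moderation (adjusted p = 0.0526, over all alternatives 0.00120 to 0.0526), and CCNG1 neither there (0.120) nor without untreated replicate 1, 3 or 4 or geneticin replicate 4 (adjusted p up to 0.0855). The p53 counts moved with single arrays, to 5 rising and 1 falling without untreated replicate 1 and 5 falling without untreated replicate 2, and only 1 fell without untreated replicate 3 or 4 or geneticin replicate 4. Without moderation 0 fell. The NRF2 and oxidative stress list had 4 of 27 rising, 3 falling and 20 not passing (6 and 4 adjusted over the list alone, camera adjusted p = 0.745). TXN, thioredoxin, rose by 0.82 ± 0.08 and GPX1, a glutathione peroxidase, by 0.72 ± 0.09, or 0.33 when its probe sets were averaged, while PGD and TKT of the pentose phosphate pathway fell by 0.50 and 0.42 (adjusted p = 3.2e-04, 0.00108, 0.00484 and 0.00176). Of its members 6 fell without untreated replicate 2, and 7 rose and 5 fell with the replicate block. For glycolysis and hypoxia, 2 of 28 rose, 5 fell and 21 did not pass (3 and 5 adjusted over the list alone, camera adjusted p = 0.730), with PFKM, a phosphofructokinase, at -0.48 ± 0.07 and BHLHE40, a hypoxia-responsive repressor, at -0.62 ± 0.10 (adjusted p = 0.00157 and 0.00268). Over all settings 1 to 5 rose and 2 to 6 fell. Of 29 immediate early genes 5 rose, 1 fell and 23 did not pass (5 and 1 adjusted over the list alone, camera adjusted p = 0.184), with the nuclear receptor NR4A2 at 0.72 ± 0.08 and the MAP kinase phosphatase DUSP4 at 0.49 ± 0.09 (adjusted p = 5.4e-04 and 0.00569). Its rising members numbered 2 or 3 with any array but geneticin replicate 3 left out, without moderation or among the brighter genes, and up to 3 fell in other settings. For phosphoinositide and calcium signalling, 5 of 31 rose, 3 fell and 23 did not pass (5 and 5 adjusted over the list alone, camera adjusted p = 0.878), with the phosphatidylinositol kinases PI4KA at -0.52 ± 0.08 and PI4K2A at 0.53 ± 0.08 (adjusted p = 0.00173 and 0.00191). Only 1 member fell without geneticin replicate 2 or 4 or after median centring, but 6 fell with the replicate block and 7 with array weights.

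Zinc and immune lists held few changes. Of 10 metallothionein and zinc response genes, MTF1, the zinc-sensing transcription factor, rose by 0.65 ± 0.11 on the log2 scale (limma adjusted p = 0.00384) and 9 did not pass, also adjusted over the list alone (camera adjusted p = 0.984). MT2A, a metallothionein, passed as lower with the replicate block alone (-0.31, or -0.45 to -0.18 with 1 array left out, adjusted p = 0.0267, against 0.252 without the block and 0.0267 to 0.492 over all alternatives). Among 28 interferon response genes IFI35 fell by 0.36 (adjusted p = 0.0143, 0.0606 without moderation and 0.00351 to 0.0606 over all alternatives) and 27 did not pass, also adjusted over the list alone (camera adjusted p = 0.878). The counts moved to 2 rising and 3 falling with the replicate block and 1 and 3 without untreated replicate 2. DDX60, a helicase, passed as lower in both, with array weights and with a trended robust prior (adjusted p = 0.0188 to 0.0399, against 0.0558 over all arrays and 0.0188 to 0.145 over all alternatives). Of 20 NF-kB and inflammatory cytokine genes 0 changed by limma, also adjusted over the list alone and without moderation, with 0 at an unadjusted p under 0.05 (camera adjusted p = 0.698). With the replicate block 1 rose. Most members of both immune lists were dim, with 3 of 20 NF-kB and 3 of 28 interferon genes above the median level of all genes. Few dim genes of the array passed (25 rising and 37 falling among the 4605 dimmest), so a lack of change there is weak evidence. Medians and tests differed in sign for p53 targets (median -0.09, mean -0.01), metallothioneins (median -0.06, mean -0.01), the NRF2 list (median -0.03, mean 0.02), histones (median -0.02, mean 0.03) and ribosomal proteins (median -0.02, mean 0.01), where camera leaned higher. With 1 array left out the last 4 of these medians changed sign (-0.16 to 0.00, -0.05 to 0.03, -0.05 to 0.01 and -0.03 to 0.02) and that of p53 targets shrank to as little as -0.02, so these signs carry no weight.

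Markers of other cell types held 1 change. By limma 0 of 14 fibroblast markers, 0 of 12 keratin epithelium markers and 0 of 13 hepatocyte markers changed, also adjusted over the list alone, and 1, 0 and 0 had an unadjusted p under 0.05 (camera adjusted p = 0.283, 0.626 and 0.730). In the other gene-level settings the only change was 1 fibroblast marker lower with the replicate block. Of these markers 3, 0 and 0 lay above the median level of all genes, as did 1 of 13 blood cell markers. Most were thus dim, where few genes passed. Of 13 blood cell markers, CD68, a lysosomal protein of macrophages, fell by 0.24 (adjusted p = 0.0303) and 12 did not pass, with 0 passing adjusted over the list alone and 3 at an unadjusted p under 0.05 (camera adjusted p = 0.247). The call for CD68 was lost without any array but untreated replicate 2 and geneticin replicate 1 (adjusted p up to 0.0880), without moderation and with a trended robust prior. Up to 2 markers fell with array weights or without untreated replicate 2. Of 18 lineage markers that HEK cells express, 1 rose, 3 fell and 14 did not pass (1 and 3 adjusted over the list alone, camera adjusted p = 0.283). VIM, vimentin, and NEFL, a neurofilament protein, fell by 0.42 and 0.31, and INA, another neuronal filament protein, rose by 0.45 ± 0.12 on the log2 scale (adjusted p = 0.00823, 0.0151 and 0.0243). INA did not pass without untreated replicate 3, geneticin replicate 1, 2 or 4 or moderation (adjusted p up to 0.107).

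**Figure D3:**
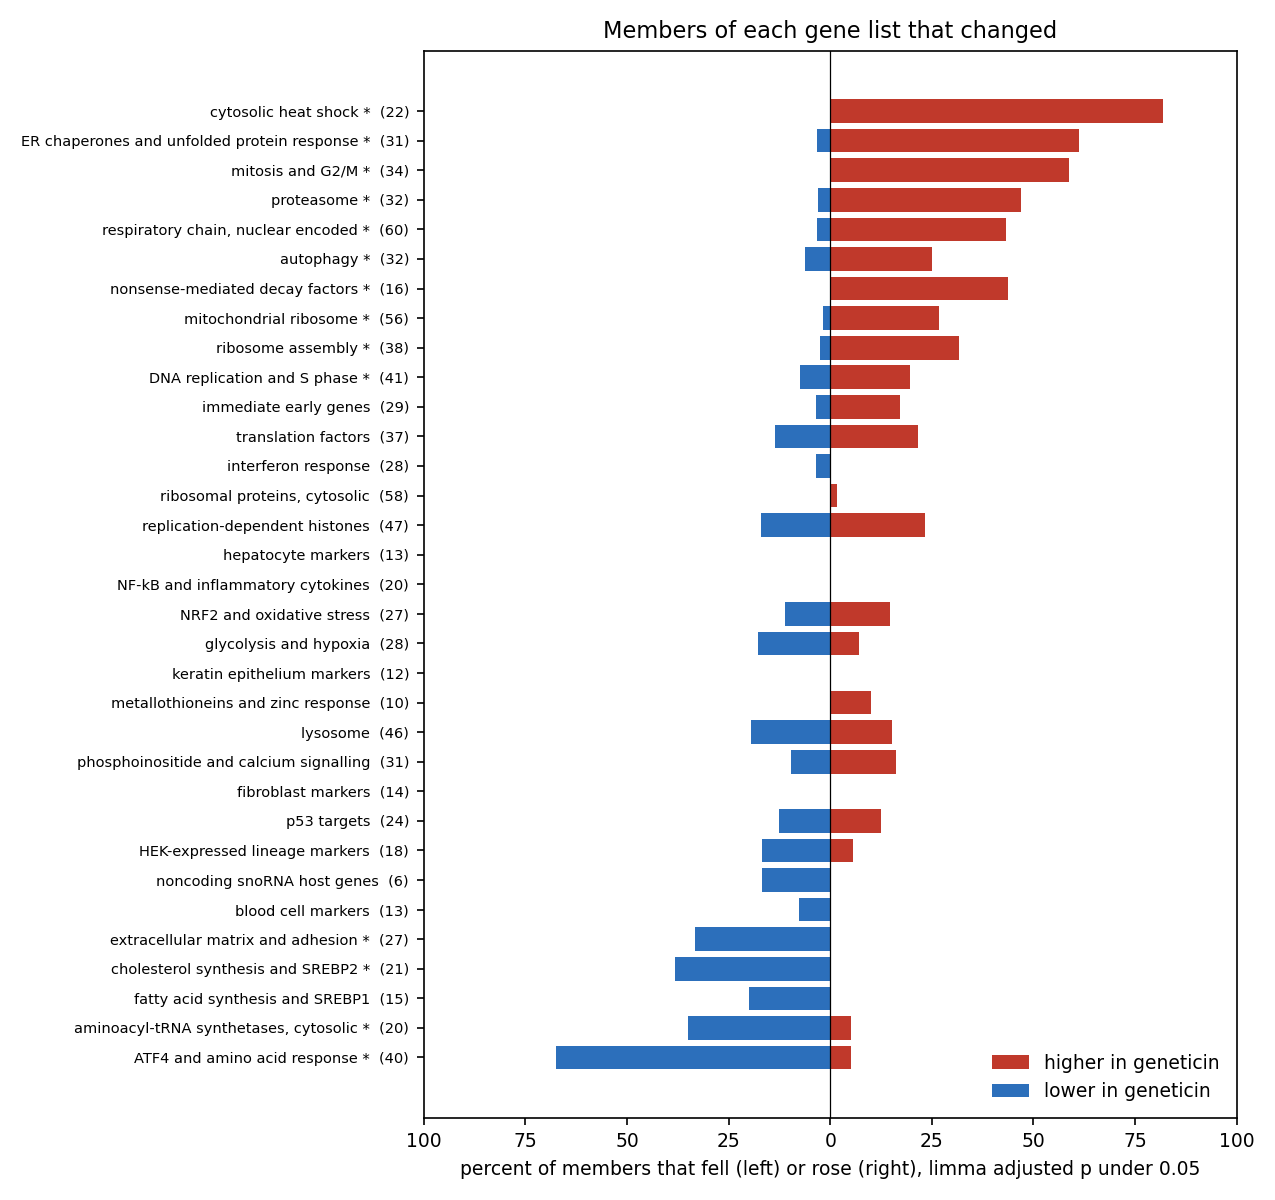
Bars give the percent of measured members of each of 33 gene lists that rose (red, right) or fell (blue, left) in geneticin at a limma adjusted p under 0.05, with the number measured in brackets and an asterisk where camera with a preset correlation passed. The heat shock list has 18 of 22 rising and the ATF4 list 27 of 40 falling.

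In all, 14 of 33 measured lists passed limma's camera test with a preset correlation, 10 higher and 4 lower, and fry and ranks gave 11 and 15. With an estimated correlation 0 passed, and 4 had an unadjusted p under 0.05. The list medians of the 14 kept their direction after quantile normalization again. They also did after median centring, but that moves every log2 fold change by the same small amount (median over all genes from -0.029 to 0.002). It could not have turned any of them. Other splits of the 8 arrays into 4 and 4 gave up to 17 lists, so the number of lists does not set treatment apart. Some of them kept part of the treatment difference, but the split with 17 had treated and untreated arrays in equal number on each side. The highest number of changed genes in any other split was 0, though each mixes treated and untreated arrays, which widens the spread within groups.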

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

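The random lists matched on mean level for lists other than the chaperone, ATF4 and respiratory chain lists were tests chosen after the results were seen. The patterns weighed here were also picked after the fits were seen, and their other tests before the tests' values were.

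The first pattern is the number of changes between the groups. Among the 35 splits of the 8 arrays into 4 and 4, only the real split gave 3139 changed genes, or 2715 over 1.2-fold. The highest count in any other split was 0 for both. The exact permutation p of the real split is thus 0.0286, the smallest that 35 splits can give, so chance is unlikely but not excluded. Every other split mixes treated and untreated arrays, which widens the spread within its groups and holds its count down. For gene lists chance cannot be excluded either. By camera with a preset correlation 8 of the 35 splits gave 14 or more, and the highest other split gave 17. Some of these splits kept most treated arrays together, but that with 17 had treated and untreated arrays in equal number on each side. Of the 14 lists that passed, 11 had a median outside the central 95% of 10000 random lists of like mean level, while nonsense-mediated decay (95.9th percentile), ribosome assembly (92.0th) and DNA replication (80.6th) did not. These random lists, like those below, hold genes drawn independently, so their ranges are narrower than those of correlated genes. The 14 lists were also called on the same fold changes, so lying outside is no separate support. A lean of bright genes, with a median log2 fold change of 0.06 among the brightest 4604, may account for the calls of ribosome assembly and DNA replication, which among the brighter genes alone were lost (adjusted p = 0.0773 and 0.196) at the same medians of 0.12 and 0.10, as was that of the mitochondrial ribosome (0.0773, median 0.11), whereas nonsense-mediated decay kept its call there (adjusted p = 0.0176, 3.3e-05 to 0.357 over all alternatives).

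The second pattern is that chaperone lists rose while the ATF4 list fell. A shift that depends on signal level and was left by the normalization would put their medians among those of random lists of like level, but 3 of the 3 medians lay outside the central 99% of such lists, with 0.65 for heat shock, 0.49 for endoplasmic reticulum chaperones and -0.48 for ATF4 against ranges of -0.10 to 0.18, -0.10 to 0.16 and -0.08 to 0.14. A single array does not set the pattern either, since the smallest share of a median kept with any 1 array left out was 0.883. The ATF4 list did vary within groups, and another split of the arrays gave it a median of 0.44 in size. What stays open is an effect of treatment on chaperone and ATF4 list genes, which these values suggest as a hypothesis only, and any handling that differed between all treated and all untreated cultures, which the labels do not describe. No list passed camera with an estimated correlation, so against other genes the pattern rests on its member genes. By fry, which tests a list on its own, the heat shock, endoplasmic reticulum chaperone and ATF4 lists passed (adjusted p = 1.1e-04, 0.00454 and 0.0145).

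The third pattern is the rise of the nuclear respiratory chain list. Genes of short genomic span did not read higher in geneticin, since the 4598 shortest had the lowest median log2 fold change of 4 span groups (-0.05, against -0.03 to -0.01). Random lists matched on level and span had 0.135 at the upper end of their central 99%, against the list's 0.18, but this was no hard test, since matching on span lowered their median from 0.04 to 0.03. Untreated replicate 2 stood apart from the other untreated arrays on component 2, and an array property shared with it would place it among the treated arrays for this list, but it lay 0.179 below the lowest of them, where the SD of the other untreated arrays was 0.0354, and without it the median kept 0.912 of its value. The medians of the span groups go against the first explanation, but these groups were not matched on signal level. The random lists matched on level and span had no higher median (0.03 against 0.04), so neither comparison shows short genes reading higher. The values of untreated replicate 2 argue against the second. Transcript length itself was not tested, and an effect of treatment, which may be on mitochondrial transcripts or on growth, stays open as a hypothesis that no further test here separates.

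Single arrays stood far from the other 3 of their group in 17 of 354 groups tested, where chance gives about 17.7, with 6 in geneticin replicate 2, 4 in untreated replicate 2 and 3 in geneticin replicate 1. In geneticin replicate 2, log2 values were 11.683 for IARS1 against 11.84 to 11.85 in the others, 9.868 for LAMC1 against 10.06 to 10.09, 9.193 for MAGOH against 8.88 to 8.93, 10.007 for MTF1 against 9.65 to 9.69, 9.617 for NDUFC1 against 9.42 to 9.45 and 9.346 for PI4KA against 9.06 to 9.10. Untreated replicate 2 had 9.697 for ASAH1 against 9.93 to 9.95, 10.207 for BUB1 against 10.08 to 10.09, 11.184 for DCP1A against 10.95 to 10.97 and 8.965 for MRPL35 against 9.16 to 9.17. Geneticin replicate 1 had 5.802 for THY1 against 6.03 to 6.05, 7.474 for TYROBP against 7.67 to 7.69 and a mean centred value of 0.185 for the autophagy list against 0.01 to 0.03. The remaining values were 10.173 for MID1IP1 in untreated replicate 1 (10.40 to 10.44 in the others), 7.225 for KRT14 in untreated replicate 4 (7.09 to 7.11), 8.126 for MRPL27 in geneticin replicate 3 (8.26 to 8.28) and 8.655 for NDUFB6 in geneticin replicate 4 (8.26 to 8.29).

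Signal also differed on probe sets outside the main test. In a limma fit of every probe set, 79 probe sets annotated to several genes were higher and 67 lower in geneticin, and of those annotated to none 208 were higher and 79 lower.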

How the results depend on the processing

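The exact permutation of list scores was chosen after seeing the data, and the other settings before. Without moderation of the variances 1723 genes changed (1028 higher, 695 lower, 1447 over 1.2-fold), of which 1641 were among the 3139, and array weights raised the number lower to 1918. Of the 2715 genes over 1.2-fold, 386 exceeded 1.5-fold and 208 passed limma's test against 1.2-fold, both stricter by construction. With 1 array left out, 1941 (without untreated replicate 3) to 3949 (without untreated replicate 2) genes changed, 1159 to 2216 higher and 782 to 1733 lower, with 1899 to 3437 over 1.2-fold, and 13 to 15 lists passed. For the shifts without moderation, with array weights or with an array left out the cause was not tested. The lists passing fell from 14 to 0 with an estimated correlation (4 at an unadjusted p under 0.05, 11 by fry, 15 by ranks), which widens the error of correlated genes. By the exact permutation of list scores 0 passed, but 35 splits give no p under 0.0286, so 19 of the 33 lists would have to reach that floor for any to pass. It was reached by 11, 10 of them among the 14 (adjusted p = 0.0857), and this 0 is no evidence on stability. The other settings kept the counts within 1.5 times, with 3122 genes after quantile normalization again, 3129 after median centring, 3079 among the brighter genes, 2638 over every probe set, 3155 with the mean of a gene's probe sets and 3152 with a trended robust prior, and the share of higher genes ran from 52.0% (quantile normalization) to 67.2% (median centring). The replicate block, which the labels' shared numbers allow but the values do not establish as a pairing (residual correlations of same-numbered arrays of -0.01, 0.44, 0.16 and 0.35), gave 4140 genes, 3083 of them among the 3139. Across groups the arrays numbered 2, 3 and 4 were each closest to the array of the same number, and those numbered 1 were not, so a partial pairing stays possible. Of 144 genes followed across settings, most of them named here, 131 changed and 104 of these did so in every setting run for them. Across 2160 comparisons with an alternative 2049 kept their call or lack of it, 99 lost it, 12 gained it and 0 reversed direction. Most of these genes were picked by p or fold change in the same fit, so the share need not hold for all genes. Of all 3139 changed genes, 1641 still passed without moderation and 1925 without untreated replicate 3. The replicate block, the trended prior and no moderation leave every fold change as it was and could not reverse a direction. Lists kept their call or lack of it in 463 of 493 comparisons, lost it in 23, gained it in 7 and reversed in 0. The share of component 1 between groups stayed between 86.3% and 95.5%. Few dim genes passed, with 25 genes rising and 37 falling among the 4605 dimmest, and whether signal over background limits them was not tested. Bright genes rose more often than dim ones and more often than they fell. In lists of mostly bright genes, such as autophagy and DNA replication, the number of rising members is thus no measure of enrichment by itself.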

Other observations

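Families of genes sharing the letters that start their symbols were tested after seeing the data. Among 247 families with at least 10 measured members, 23 were higher and 4 lower by camera with a preset correlation, 0 passed with an estimated correlation (lowest adjusted p = 0.588), and 10 had an unadjusted p under 0.05 with it. Subunits of the endoplasmic reticulum membrane complex, which inserts membrane proteins, had 6 of 10 members rising and 1 falling, with EMC8 at 0.75 ± 0.10 and EMC3 at 0.62 ± 0.06 on the log2 scale (SE, n = 4, limma adjusted p = 0.00121 and 4.1e-04). EMC10 fell by 0.30 (adjusted p = 0.0329), a call lost without untreated replicate 1, 3 or 4, geneticin replicate 1 or 2 or moderation (adjusted p up to 0.0952). The camera adjusted p was 0.0129, and the adjusted p = 0.935 with an estimated correlation. Of 11 PRPF splicing factors 6 rose and 0 fell, with PRPF4 at 0.73 ± 0.08 and PRPF18 at 0.50 ± 0.09 (limma adjusted p = 6.2e-04 and 0.00517, camera adjusted p = 0.00396, adjusted p = 0.935 with an estimated correlation).

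Histone lysine demethylases of the KDM family had 8 of 18 members rising and 1 falling, with KDM4D at 0.67 ± 0.11 and KDM6A at 0.50 ± 0.08 on the log2 scale (limma adjusted p = 0.00275 for each, camera adjusted p = 0.00444, adjusted p = 0.935 with an estimated correlation). KDM8 fell by 0.49 (adjusted p = 0.0130), or by 0.19 when its probe sets were averaged (adjusted p = 0.123), and did not pass without moderation (0.0750). KLF transcription factors moved the other way, with 6 of 18 falling and 0 rising, among them KLF8, which fell by 0.82 (SE 0.10), and KLF11, which fell by 0.60 (SE 0.06), with limma adjusted p of 9.4e-04 and 4.4e-04 (camera adjusted p = 0.00304, adjusted p = 0.662 with an estimated correlation). Of 494 zinc finger genes of the ZNF family, 81 rose and 18 fell, with a median of 0.07 (camera adjusted p = 0.00262, adjusted p = 0.935 with an estimated correlation).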
